A study of Homo sapiens with 8 samples.

How the data were processed

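Polyadenylated RNA of SH-SY5Y cells was sequenced in 8 libraries, 2 biological replicates for each of 4 siRNAs, with groups and replicate numbers taken from the labels. Per the labels' protocols, cells were transfected with 25 pmol of siRNA per well with a lipid reagent, RNA was isolated with Trizol and libraries were made with a TruSeq kit after poly(A) selection. The deposited values are raw read counts per gene symbol, 58581 symbols per library, with 5 summary entries that name no gene. The authors made these counts before deposit with bcl2fastq 2.17.1.14, STAR 2.5.0a, HTSeq 0.8.0 and build hg38, per the submitters' processing notes, which also name DESeq2 and give neither the role nor the order of the tools. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain. The entries that name no gene stayed out of library sizes and tests. Of the gene counts and summary entries together, 5.36% to 7.02% fell in no feature, 5.83% to 6.77% were ambiguous between genes and 16.6% to 28.5% did not align uniquely.

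Gene counts per library ran from 33548173 to 42023687, so counting error is small for genes with many reads. It is larger for named genes at low levels, among them MMP1 with siRNA 3 and some list members, for which no minimum CPM was set. The biological coefficient of variation common to all genes was 7.95%. Mitochondrially encoded genes took 3.46% to 5.21% of the counts. Positions, gene types, GC content and 3' UTRs came from the GENCODE annotation of GRCh38, and older gene symbols were matched through RefSeq names. A GC value was found for 84.4% of the tested genes and 95.3% of those called in the average of the siRNAs.

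Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr by group, which left 18962 genes, libraries were scaled with TMM factors (0.966 to 1.06), and a quasi-likelihood model with 4 groups was fitted to all 8 libraries with robust estimation, so that groups share an estimate of the spread. Tested were each siRNA against scramble, the mean of the 3 siRNAs against scramble, the pairs of siRNAs and any difference among the 3 siRNAs. Each siRNA had its own mean in this model, so differences between siRNAs did not enter the spread behind the average. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 per comparison. A gene changed the same way with all 3 siRNAs when it passed all 3 single tests with 1 sign. Printed fold changes are the fitted ones, and each standard error is the fold change divided by the square root of its F statistic. Correlations between siRNAs and the count of genes changed the same way with all 3 were set beside those of 20 simulations of unchanged groups against the same scramble libraries, drawn with the fitted spread. Overlaps of pairs of siRNAs were set beside those of independent lists.

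Lists of genes, 25 in all, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 at a preset inter-gene correlation of 0.01, with adjustment over the 25 lists, and beside it with an estimated correlation and with fry. The lists cover replication-dependent histones, retinoic acid response, hypoxia and glycolysis, oxidative phosphorylation, the ATF4 stress response, ER chaperones, cholesterol synthesis, G1/S replication, G2/M mitosis, p53 targets, interferon response, immediate early genes, small RNA silencing machinery, mitochondrially encoded genes, the Notch and Wnt pathways, axon guidance, neuronal cytoskeleton and neurite, synapse and vesicle release, neurosecretory granule, noradrenergic identity, substrate-adherent mesenchymal, Schwann and glial, neural progenitor and Cajal-Retzius cell markers. With an estimated correlation 0 of the 25 lists passed in any of the 7 comparisons, the lowest adjusted p being 0.136. Of the lists past the preset test, 2 of 4 in the average, 4 of 8 with siRNA 1, 1 of 6 with siRNA 2 and 4 of 8 with siRNA 3 also passed with fry, which asks whether a list moves on balance one way and compares it with no other genes. For each list past the test, the median, the mean and the test had the same sign.

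The comparisons, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except the correction for GC content and the search of 3' UTRs and junctions. By that rule the text names SLC45A4, the 12 genes with the highest and the 12 with the lowest average fold change among those changed the same way with all 3 siRNAs, the 6 highest and 6 lowest per siRNA with both libraries outside the scramble range, the 6 with the smallest p among siRNAs and up to 4 members of each list with the smallest p in the average, with a mean CPM of at least 5 except for list members. Some genes that this rule selects are not reported here. Alternatives were RLE factors, library sizes alone, no low-count filter, at least 1 CPM in 4 libraries, the replicate number as a block, each library left out, DESeq2 1.42.0, a 1.5-fold minimum, the 6 siRNA libraries pooled, each siRNA left out of the average and fits of only the 4 libraries compared. The GC correction, chosen after the data were seen, removed from each library the trend of log2 CPM on GC content (lowess, span 0.3) through an offset.

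The model was tested on simulated counts with 200 genes changed among 18962. For the average of the siRNAs it recovered 63% of the genes changed 1.5-fold and 72% of those changed 2-fold, and 4.93% of its calls were false. For siRNA 1 against scramble it recovered 51% and 67%, with 7.81% false. Of 200 genes changed with all 3 siRNAs, 106 were found and 0 others. A list changed 1.3-fold in the average passed camera's test at the preset correlation (adjusted p = 2.19e-28), with 0 unchanged lists called. Genes were drawn independently of each other, so this trial does not measure false calls under correlation between genes. In counts with a GC trend added for the average, the correction brought the correlation of fold and GC content from 0.732 to 0.00703. False calls numbered 2228 among all 18962 genes before it and 10 among the 16003 genes with a GC value after it.

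Words of 7 bases in annotated 3' UTRs were scored for each group against the mean of the other groups in 11859 genes with a 3' UTR of at least 50 bases and a mean log2 CPM of at least 1. For 16225 words found in at least 50 genes, the score z compared the fold changes, clipped at 3 median absolute deviations, of genes with and without the word after the trends with the GC content of gene and UTR, UTR length and expression were removed, and 100 permutations of the genes gave the range with no relation. In simulated data with a shift of 0.1 for genes with a word, the word ranked first in 20 of 20 trials, and smaller shifts were not simulated. The search used Biostrings 2.70.1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the annotation, the junction search and the plots.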

Results

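SH-SY5Y, an established human neuroblastoma cell line with traits of sympathetic neuron precursors, was transfected with siRNAs against circSLC45A4, a circular RNA that back-splicing makes from the SLC45A4 gene. Cells received siRNA 1, siRNA 2, siRNA 3 or a scrambled siRNA at 25 pmol per well, and the polyadenylated RNA of 2 biological replicates per siRNA was sequenced, which gave 8 libraries in 4 groups. Reads assigned to genes numbered 42023687 and 38521747 in the siRNA 1 libraries and 33548173 and 41466809 in the siRNA 2 libraries. They numbered 34634403 and 34279022 with siRNA 3 and 33562724 and 38041545 with scramble. Between 25475 and 29178 genes had at least a single read per library. Across genes, log2 counts scaled to library size (CPM) of the replicates of a group correlated at 0.991 to 0.995, and each pair of replicates differed by more than sampling noise (chi-square per degree of freedom 9.61 to 18.32). Every fold change is a log2 value with its standard error (SE) from a fit of all 8 libraries, with n = 2 libraries per group. Every adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 18962 genes unless a gene list is named.

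SLC45A4, the host gene of the targeted circle, encodes a membrane transport protein and lies on chromosome 8 at 141207166 to 141308305, on the minus strand of GRCh38. Its gene count was 19.0 ± 1.08 CPM with scramble (SD, n = 2), 19.9 ± 1.41 with siRNA 1, 25.0 ± 0.632 with siRNA 2 and 22.5 ± 2.19 with siRNA 3. SLC45A4 rose with siRNA 2 by 0.39 (SE 0.11, adjusted p = 0.0282), while the change was 0.06 with siRNA 1 (adjusted p = 0.717), 0.24 with siRNA 3 (adjusted p = 0.199) and 0.23 in the average of the 3 siRNAs (SE 0.091, adjusted p = 0.086). The average passed the threshold with library sizes as the only scaling (0.28) and with siRNA 1 left out of the average (0.32). It was 0.13 after the correction for GC content (adjusted p = 0.233) and 0.15 with siRNA 2 left out (adjusted p = 0.302). The count of this gene comes mainly from linear, polyadenylated RNA, so it did not measure the circle and did not check its knockdown. SLC45A4-AS1 overlaps the gene on the other strand, and the strand setting of the counting is not given in the sources used here, so reads of this pair of genes could not be told apart.

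The first comparison asked which genes responded to the siRNAs in common. IFITM2, a membrane protein induced by interferon that restricts virus entry (chromosome 11, 307631 to 315272), fell from 9.75 ± 0.0732 CPM with scramble to 4.59 ± 0.318, 4.94 ± 0.357 and 3.25 ± 0.241 CPM with siRNA 1, siRNA 2 and siRNA 3 (SD, n = 2), an average of -1.22 (SE 0.11, adjusted p = 4.17e-06). NTRK2, the receptor of brain-derived neurotrophic factor (chromosome 9, 84668551 to 85027070), fell by 1.01 (SE 0.1, adjusted p = 1.39e-05), from 14.1 ± 1.4 CPM to between 6.05 ± 0.707 and 7.58 ± 0.168 CPM. TIMM17B, a subunit of the protein import channel of the inner mitochondrial membrane (chromosome X, 48893447 to 48898143), rose by 1.41 (SE 0.092, adjusted p = 6.52e-08), from 24.3 ± 0.118 CPM with scramble to 60.0 ± 1.87, 66.3 ± 8.87 and 67.8 ± 5.66 CPM. PRKCA, the alpha form of protein kinase C, rose by 0.96 (SE 0.077, adjusted p = 9.97e-07), from 213 ± 11.9 CPM to between 391 ± 12.2 and 435 ± 27.5 CPM.

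Genes that changed the same way with all 3 siRNAs numbered 346, of which 178 were higher and 168 lower than with scramble (27 and 236 without scramble replicate 1), and 35 of them changed at least 2-fold on average. The 12 with the largest falls also included the neuronal fate factor NEUROG2 (-0.97, SE 0.15), the adenosine receptor ADORA1 (-0.83, SE 0.13), the secretory vesicle GTPase RAB27B (-1.04, SE 0.16), the fatty acid binding protein FABP5 (-0.83, SE 0.097), the leptin receptor LEPR (-0.82, SE 0.15) and the extracellular matrix genes MGP (-0.83, SE 0.11) and ELN, which encodes elastin (-0.82, SE 0.075). The small heat shock protein HSPB7, the lipid transporter ABCA12 and ELMOD2 completed that group, at -1.01, -0.95 and -0.87. The 12 with the largest rises also included the adhesion receptor ADGRG1 (1.26, SE 0.15), the endocytic protein SH3GL1 (0.98, SE 0.084), the semaphorin receptor PLXNB2 (0.75, SE 0.083), KIAA1549 (0.82, SE 0.084), KIAA1683 (1.26, SE 0.14), the histone gene HIST1H2BD (0.79, SE 0.14) and ARHGAP33 (0.76, SE 0.12). CEP170B, TNRC18 and the processed pseudogene CICP14 rose by 0.77, 0.72 and 0.76. IFITM2, HIST1H2BD and CICP14 belong to families of near-identical copies, so their counts are uncertain where reads were shared. The GC content of the 12 that rose was 47.5% to 67.1%, and that of the 12 that fell 33.6% to 61.6%. Each of these genes kept its average call when any 1 library was left out and after a correction for the trend with GC content. With the 6 siRNA libraries pooled as 1 group, IFITM2, NTRK2, ELMOD2, MGP, LEPR, TIMM17B, SH3GL1, PRKCA, KIAA1549 and PLXNB2 still passed the threshold and the others did not.

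**Figure D1:**
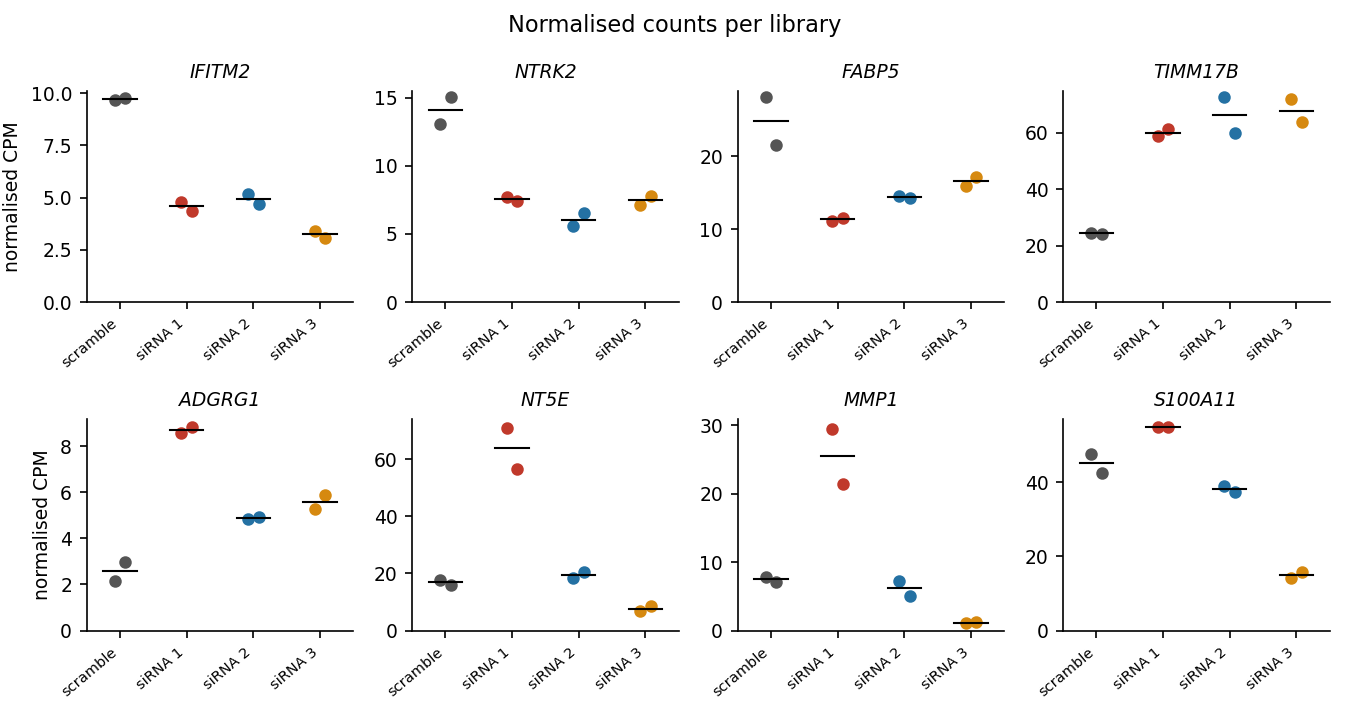
Normalised CPM of 8 named genes by group, with a point for each library and a bar for the mean of 2. IFITM2, NTRK2 and FABP5 lie lower and TIMM17B and ADGRG1 higher with each siRNA than with scramble, while NT5E, MMP1 and S100A11 lie higher with siRNA 1 than with siRNA 3.

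In the average of 3 siRNAs against scramble, 3268 of 18962 genes differed, 1413 higher and 1855 lower, 193 of them at least 2-fold. The spread behind this test leaves out differences between siRNAs, so a change with 1 siRNA alone can give a call. Of the calls, 43.2% were higher, against 63% with library sizes as the only scaling, and the share was 51.4% against 69% among the genes that changed the same way with all 3. Without scramble replicate 1 these shares were 24.3% and 10.3%, and without scramble replicate 2 they were 48.5% and 71.4%. Of 26 measured replication-dependent histone genes, 8 rose, 0 fell and 18 were not called (8 higher adjusted over the list alone), with a median of 0.57. HIST1H1C (0.69, SE 0.096) and HIST1H2BJ (1.01, SE 0.18) were examples, and the list passed camera's test (adjusted p = 1.59e-06, and adjusted p = 0.694 with an estimated correlation). Most transcripts of such genes carry no poly(A) tail, so these libraries held mainly their polyadenylated forms, at mean levels of 0.184 to 23.1 CPM per gene. Of 15 measured retinoic acid response genes, 6 fell, 1 rose and 8 were not called (8 lower and 1 higher adjusted over the list alone). The retinoic acid receptor RARB fell by 0.69 (SE 0.099) and the transglutaminase TGM2 by 0.73 (SE 0.081), both of them with each siRNA, while STRA6, which takes up retinol, rose by 0.38 (SE 0.076). The list passed the test (adjusted p = 0.0182, and adjusted p = 0.738 with an estimated correlation).

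Of 26 hypoxia and glycolysis genes, 8 fell and 18 were not called (8 lower adjusted over the list alone), among them the pyruvate dehydrogenase kinase PDK1 (-0.67, SE 0.079) and the aldolase ALDOC (-0.48, SE 0.089). That list passed at adjusted p = 0.00879, with adjusted p = 0.89 with an estimated correlation. Of 36 oxidative phosphorylation genes, 5 fell and 31 were not called (2 lower adjusted over the list alone), with NDUFB5 of complex I at -0.28 (SE 0.076) and the ATP synthase subunit ATP5O at -0.33 (SE 0.097), and the list passed at adjusted p = 0.0233 (adjusted p = 0.89 with an estimated correlation). In the average of 3 siRNAs against scramble, the hypoxia call ended without siRNA 3 replicate 2 (adjusted p = 0.0638) or scramble replicate 1 (0.0544), and the retinoic acid call without siRNA 3 replicate 2 (0.0627) or with the stricter filter (0.052). The oxidative phosphorylation call ended without siRNA 1 replicate 1 (0.0992), siRNA 2 replicate 2 (0.104), siRNA 3 replicate 2 (0.0719) or scramble replicate 1 (0.285) and with the stricter filter (0.052), and the count of genes in the average was 48 with the 6 siRNA libraries pooled as 1 group, 1390 (338 higher) without scramble replicate 1, 1701 without scramble replicate 2 and 1832 without siRNA 1 replicate 1.

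**Figure D2:**
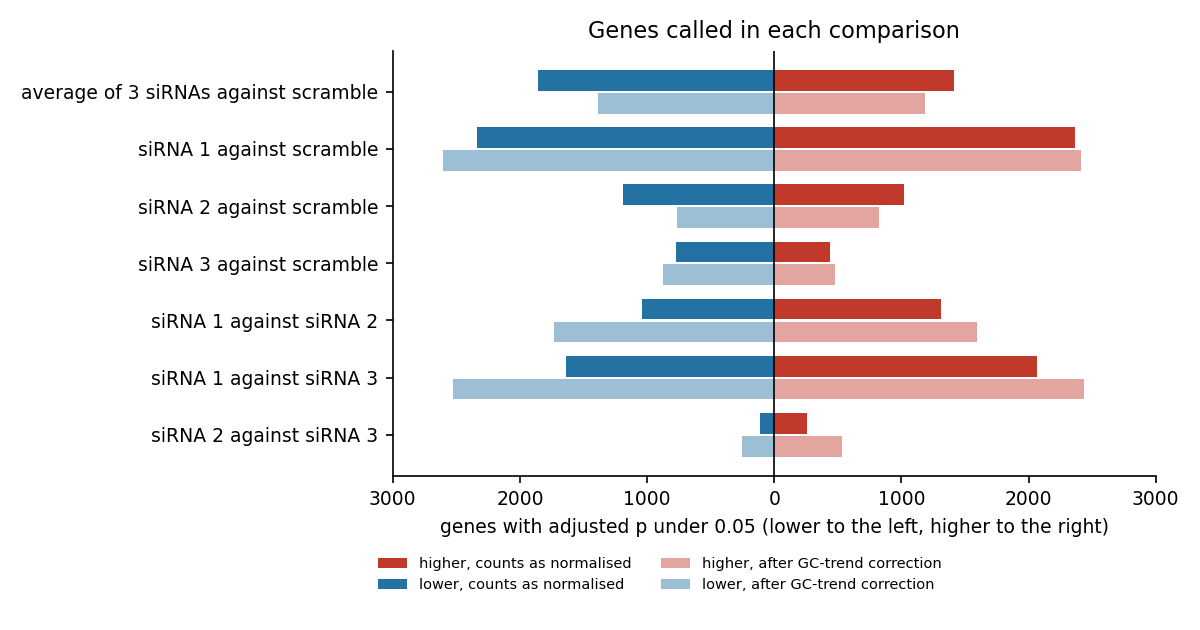
Number of genes past the threshold in each comparison, higher to the right and lower to the left, before (dark) and after (pale) the correction for GC content. siRNA 1 had 4701 calls against scramble, siRNA 2 had 2215 and siRNA 3 had 1212, and siRNA 1 and siRNA 3 differed in 3709 genes.

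The largest rises with siRNA 1 included some genes of the cell surface and the pericellular matrix. ITGA6, an integrin chain that binds laminin, rose by 2.10 (SE 0.17, adjusted p = 8.31e-07), NT5E, the cell surface enzyme that makes adenosine from AMP, by 1.91 (SE 0.13, adjusted p = 1.37e-07) and the collagenase MMP1 by 1.77 (SE 0.17, adjusted p = 6.26e-06). PDE3A, a phosphodiesterase that breaks down cyclic AMP, fell by 2.00 (SE 0.13, adjusted p = 7.68e-08), from 25.4 ± 1.99 CPM to 6.33 ± 0.823 CPM. Lower levels were also found for FBP1 of gluconeogenesis (-1.55), RFC3 of the replication clamp loader (-1.33), the ribosomal protein paralog RPL22L1 (-1.30), NEUROG2 (-1.34) and TMEM99 (-1.34), and KIAA1683 (1.80) and ADGRG1 (1.75) were the other large rises. In all, 4701 genes differed, 2362 higher and 2339 lower, and 723 of them at least 2-fold. The share of calls that were higher was 50.2%, 43.1% with DESeq2 and 76.6% with library sizes as the only scaling, which moved the median of all genes from 0.0132 to 0.13.

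Of 27 measured markers of substrate-adherent mesenchymal neuroblastoma cells, 12 rose with siRNA 1, 3 fell and 12 were not called (14 higher and 4 lower adjusted over the list alone). FOSL1, an AP-1 transcription factor, rose by 1.10 (SE 0.17) and the collagen crosslinking enzyme LOX fell by 1.01 (SE 0.16). The list passed the test (adjusted p = 0.0131, and adjusted p = 0.709 with an estimated correlation). Of 23 noradrenergic identity genes, 11 fell with siRNA 1, 4 rose and 8 were not called (12 lower and 5 higher adjusted over the list alone), with monoamine oxidase MAOA at -0.97 (SE 0.093) and the decarboxylase DDC at -0.82 (SE 0.093), but the list as a whole did not pass (adjusted p = 0.107, and 0.0192 after the correction for GC content, where it was 0.657 with an estimated correlation). Of 27 ATF4 stress response genes, 12 fell, 0 rose and 15 were not called (13 lower and 1 higher adjusted over the list alone), among them the folate enzymes ALDH1L2 (-0.89, SE 0.11) and MTHFD2 (-0.75, SE 0.09) and PSAT1 of serine synthesis (-0.60, SE 0.089). The ATF4 list passed at adjusted p = 0.000101 (adjusted p = 0.415 with an estimated correlation). Of 33 G1/S replication genes, 12 fell and 21 were not called (14 lower adjusted over the list alone), with EXO1 at -0.56 (SE 0.092) and RRM2 at -0.36 (SE 0.082). The G1/S list passed at adjusted p = 0.000149 (adjusted p = 0.709 with an estimated correlation). Of 34 G2/M mitosis genes, 6 fell, 1 rose and 27 were not called (6 lower and 1 higher adjusted over the list alone), with CDK1 at -0.54 (SE 0.092). The G2/M list passed at adjusted p = 0.00599 (adjusted p = 0.709 with an estimated correlation).

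Of the 26 hypoxia and glycolysis genes, 10 fell with siRNA 1, 2 rose and 14 were not called (11 lower and 2 higher adjusted over the list alone), with PDK1 at -0.96 (SE 0.1) and ALDOC at -0.88 (SE 0.11). The hypoxia list passed at adjusted p = 0.000101 (adjusted p = 0.709 with an estimated correlation). Of the 36 oxidative phosphorylation genes, 7 fell and 29 were not called (7 lower adjusted over the list alone). The oxidative phosphorylation list passed at adjusted p = 0.00306 (adjusted p = 0.84 with an estimated correlation). Of the 26 histone genes, 8 rose and 18 were not called (8 higher adjusted over the list alone). The histone list passed at adjusted p = 0.000101 (adjusted p = 0.415 with an estimated correlation). Of the 15 retinoic acid response genes, 6 fell, 1 rose and 8 were not called (7 lower and 1 higher adjusted over the list alone). The retinoic acid list passed at adjusted p = 0.00385 (adjusted p = 0.415 with an estimated correlation). In siRNA 1 against scramble, without scramble replicate 1 the mesenchymal call (adjusted p = 0.0513) and the mitosis call (0.0695) ended and 3043 genes remained past the threshold, and without siRNA 1 replicate 1 the oxidative phosphorylation call ended (0.0588) and 1277 genes passed. The mitosis call also ended after the correction for GC content (0.131).

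With siRNA 2, ABCA12, which moves lipids across membranes, fell by 1.63 (SE 0.12, adjusted p = 7.56e-07), from 82.1 ± 2.55 CPM to 26.4 ± 4.96 CPM, and NTRK2 fell by 1.22 (SE 0.14, adjusted p = 3.98e-05). The ankyrin repeat gene ANKRD1 (-1.50, SE 0.16), the calcium binding protein S100A4 (-1.28, SE 0.13), the matrix proteoglycan LUM (-1.17, SE 0.11) and the steroid sulfatase STS (-1.17, SE 0.15) also fell. TIMM17B rose by 1.45 (SE 0.11), the protocadherin FAT1 by 1.38 (SE 0.14), the immediate early factor FOS by 1.38 (SE 0.11), the receptor tyrosine kinase AXL by 1.10 (SE 0.2) and SH3GL1 by 1.08 (SE 0.097). IGF2, a growth factor, passed only narrowly (1.07, SE 0.27, adjusted p = 0.0495). Of 18962 genes, 2215 differed, 1024 higher and 1191 lower, 160 of them at least 2-fold.

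Of 22 measured immediate early genes, 8 rose with siRNA 2 and 14 were not called (10 higher and 3 lower adjusted over the list alone), FOS, SPRY4 (0.73, SE 0.091) and JUN (0.40, SE 0.1) among them. The immediate early list passed at adjusted p = 0.00786 (adjusted p = 0.716 with an estimated correlation). Of 25 p53 targets, 6 rose, 1 fell and 18 were not called (8 higher and 2 lower adjusted over the list alone), with the death receptor TNFRSF10B at 0.57 (SE 0.085) and the exonuclease AEN at 0.53 (SE 0.087). The p53 list passed at adjusted p = 0.0488 (adjusted p = 0.606 with an estimated correlation). Of 23 noradrenergic identity genes, 7 rose, 1 fell and 15 were not called (7 higher and 1 lower adjusted over the list alone), with CYB561 at 0.45 (SE 0.084) and the lineage factor GATA2 at 0.35 (SE 0.092). The noradrenergic list passed at adjusted p = 0.0365 (adjusted p = 0.823 with an estimated correlation). Of 26 histone genes, 4 rose and 22 were not called (6 higher adjusted over the list alone). The histone list passed at adjusted p = 2.67e-05 (adjusted p = 0.606 with an estimated correlation). Of 34 G2/M genes, 7 fell and 27 were not called (10 lower adjusted over the list alone), with CDK1 at -0.49 (SE 0.092). The G2/M list passed at adjusted p = 0.0155 (adjusted p = 0.716 with an estimated correlation). Of 36 oxidative phosphorylation genes, 4 fell and 32 were not called (4 lower adjusted over the list alone). The oxidative phosphorylation list passed at adjusted p = 0.0249 (adjusted p = 0.823 with an estimated correlation). In siRNA 2 against scramble, without scramble replicate 1 the calls of the mitosis (adjusted p = 0.193), immediate early (0.104), noradrenergic (0.249), oxidative phosphorylation (0.206) and p53 (0.135) lists ended and 1165 genes passed (291 higher and 874 lower), and without siRNA 2 replicate 2 the noradrenergic (0.131), oxidative phosphorylation (0.799) and p53 (0.103) calls ended and 1255 genes passed. The p53 call also ended without scramble replicate 2 or any 1 of the siRNA 1 and siRNA 3 libraries (0.0632 to 0.097), with the replicate number as a block (0.101) and with the stricter filter (0.053). The noradrenergic (0.319) and mitosis (0.195) calls ended after the correction for GC content, IGF2 lost its call without siRNA 2 replicate 1 (adjusted p = 0.281) or siRNA 2 replicate 2 (0.211) and without any 1 of the scramble or siRNA 1 libraries (0.0841 to 0.123), and 1273 genes passed without scramble replicate 2 (720 higher and 553 lower) and 1272 without siRNA 2 replicate 1.

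The largest falls with siRNA 3 included a gene of matrix turnover and S100 calcium binding proteins, beside genes of other functions. MMP1 fell by 2.73 (SE 0.23, adjusted p = 3.99e-06), from 7.48 ± 0.51 CPM to 1.12 ± 0.0871 CPM, S100A10 by 1.72 (SE 0.12, adjusted p = 6.03e-08), S100A11 by 1.58 (SE 0.1, adjusted p = 6.03e-08), LUM by 1.60 (SE 0.11), ANKRD1 by 1.62 (SE 0.16) and IFITM2 by 1.58 (SE 0.15). TIMM17B (1.48), KIAA1683 (1.31), ADGRG1 (1.11), SH3GL1 (1.10) and HIST1H2BD (0.94) had the largest rises. In all, 1212 genes differed, 439 higher and 773 lower, 211 of them at least 2-fold.

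Of the 27 mesenchymal markers, 11 fell with siRNA 3, 0 rose and 16 were not called (14 lower and 1 higher adjusted over the list alone), with the intermediate filament gene VIM at -0.92 (SE 0.096) and S100A6 at -0.53 (SE 0.1). The mesenchymal list passed at adjusted p = 3.2e-05 (adjusted p = 0.412 with an estimated correlation). Of 31 measured interferon response genes, 9 fell, 1 rose and 21 were not called (11 lower and 1 higher adjusted over the list alone), with DDX60 at -1.26 (SE 0.2) and BST2 at -0.92 (SE 0.23) against IRF7 at 0.67 (SE 0.2). The interferon list passed at adjusted p = 0.00137 (adjusted p = 0.317 with an estimated correlation). Of 23 noradrenergic identity genes, 4 rose, 1 fell and 18 were not called (5 higher and 1 lower adjusted over the list alone), with GATA2 at 0.50 (SE 0.092). The noradrenergic list passed at adjusted p = 0.0317 (adjusted p = 0.672 with an estimated correlation). Of 29 neuronal cytoskeleton and neurite genes, 3 rose, 1 fell and 25 were not called (10 higher and 2 lower adjusted over the list alone), with the axonal motor KIF5A at 0.37 (SE 0.093). The neuronal list passed at adjusted p = 0.0317 (adjusted p = 0.558 with an estimated correlation). Of 38 synapse and vesicle release genes, 6 rose, 1 fell and 31 were not called (12 higher and 2 lower adjusted over the list alone), with the active zone gene BSN at 0.57 (SE 0.11) and NLGN2 at 0.39 (SE 0.099). The synapse list passed at adjusted p = 0.0236 (adjusted p = 0.636 with an estimated correlation).

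Of 33 G1/S replication genes, 3 rose with siRNA 3 and 30 were not called (5 higher adjusted over the list alone). The G1/S list passed at adjusted p = 0.0222 (adjusted p = 0.656 with an estimated correlation). Of 26 histone genes, 6 rose and 20 were not called (10 higher adjusted over the list alone). The histone list passed at adjusted p = 5.88e-05 (adjusted p = 0.412 with an estimated correlation). Of 15 retinoic acid response genes, 5 fell, 1 rose and 9 were not called (6 lower and 1 higher adjusted over the list alone). The retinoic acid list passed at adjusted p = 0.0172 (adjusted p = 0.412 with an estimated correlation). In siRNA 3 against scramble, without scramble replicate 1 the calls of the neuronal (adjusted p = 0.298), noradrenergic (0.298) and synapse (0.179) lists ended and 754 genes passed (90 higher and 664 lower), without siRNA 3 replicate 1 the same 3 calls ended (0.053, 0.375 and 0.068) and 394 genes passed, and the noradrenergic call also ended after the correction for GC content (0.274). Without siRNA 3 replicate 2 the G1/S (0.0701), neuronal (0.0675) and retinoic acid (0.0716) calls ended, and the G1/S call also without scramble replicate 2 (0.0738).

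**Figure D3:**
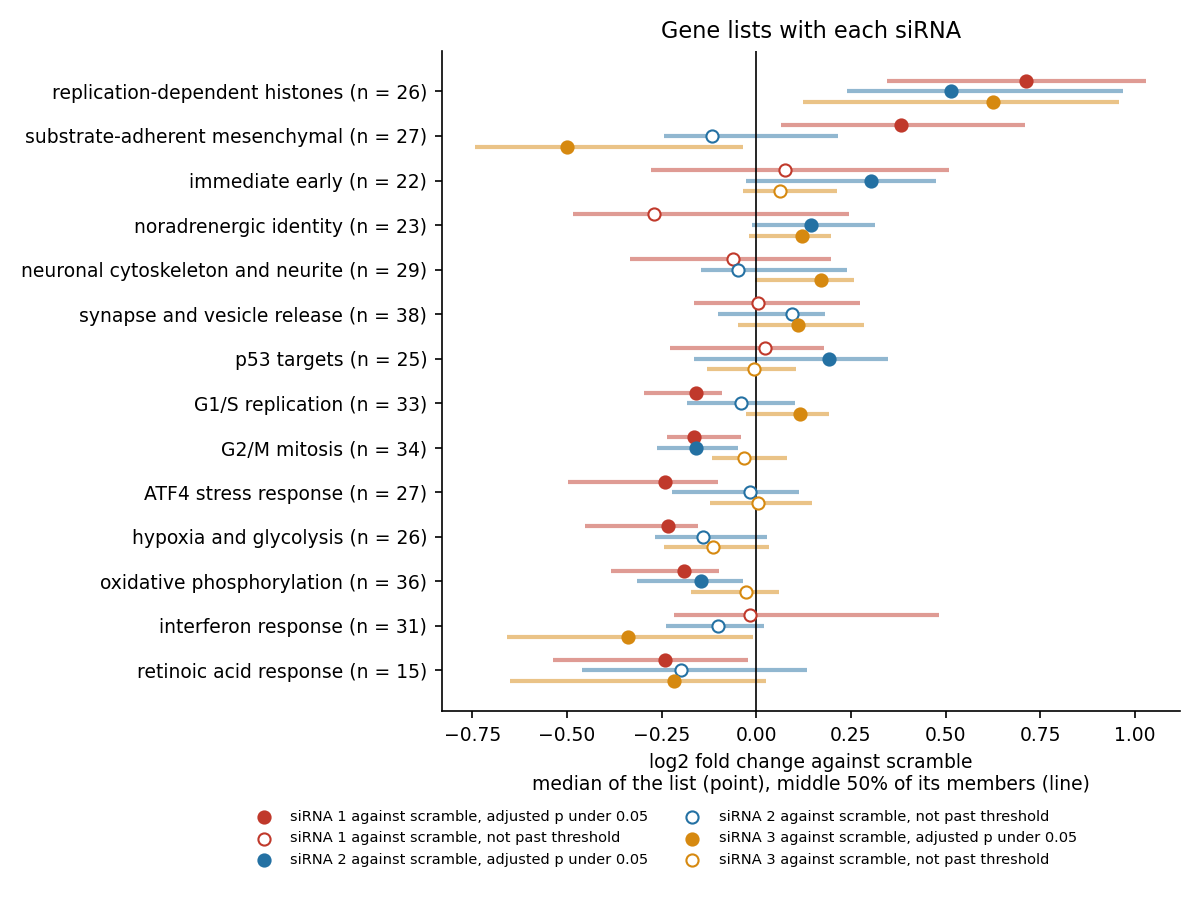
Median log2 fold change against scramble of the measured members of 14 gene lists, for siRNA 1, siRNA 2 and siRNA 3, with lines over the middle 50% of the members and filled points for lists past the threshold. The mesenchymal list lies at 0.38 with siRNA 1 and at -0.50 with siRNA 3, and the histone list lies above 0 with each siRNA.

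The next comparison asked whether the siRNAs, which share a target by design, had the same effects. NT5E, on chromosome 6 at 85449584 to 85495791, was 3.05 higher with siRNA 1 than with siRNA 3 on the log2 scale (SE 0.14, adjusted p = 3.21e-10). Its levels were 63.8 ± 10 CPM with siRNA 1 and 7.68 ± 1.32 CPM with siRNA 3 (SD, n = 2), and 19.4 ± 1.6 CPM with siRNA 2. MMP1, on chromosome 11 at 102789920 to 102798160, was 4.50 higher (SE 0.22, adjusted p = 2.59e-09), at 25.5 ± 5.71 CPM against 1.12 ± 0.0871 CPM. S100A11 (1.86, SE 0.1), the actin crosslinker FLNC (1.83, SE 0.11) and the proteoglycan SPOCK1 (1.35, SE 0.097) were also higher with siRNA 1 than with siRNA 3. These genes had some of the smallest p among 3627 genes that differed among the 3 siRNAs.

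Mesenchymal markers separated all pairs of siRNAs. Between siRNA 1 and siRNA 3, 18 of 27 members were higher with siRNA 1, 1 was lower and 8 were not called (18 higher and 2 lower adjusted over the list alone), with a median of 0.89, VIM at 1.03 (adjusted p = 4.87e-07) and FOSL1 at 1.07 (adjusted p = 0.000235), and the list passed at adjusted p = 1.12e-06 (adjusted p = 0.247 with an estimated correlation). Noradrenergic identity genes went the other way, with 11 of 23 lower with siRNA 1 than with siRNA 3, 3 higher and 9 not called (13 lower and 3 higher adjusted over the list alone). The noradrenergic list passed at adjusted p = 0.000693 (adjusted p = 0.548 with an estimated correlation). G1/S genes were lower with siRNA 1 in 18 of 33 cases, higher in 0 and not called in 15 (25 lower adjusted over the list alone). The G1/S list passed at adjusted p = 2.14e-09 (adjusted p = 0.247 with an estimated correlation). ATF4 genes were lower in 12 of 27 cases with 15 not called (14 lower adjusted over the list alone). The ATF4 list passed at adjusted p = 1.9e-06 (adjusted p = 0.247 with an estimated correlation). Interferon response genes were higher with siRNA 1 in 10 of 31 cases, lower in 1 and not called in 20 (11 higher and 1 lower adjusted over the list alone). The interferon list passed at adjusted p = 0.000693 (adjusted p = 0.247 with an estimated correlation).

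Between siRNA 1 and siRNA 2, 12 of 27 mesenchymal markers were higher with siRNA 1, 2 lower and 13 not called (15 higher and 4 lower adjusted over the list alone). The mesenchymal list passed at adjusted p = 0.0011 (adjusted p = 0.481 with an estimated correlation). Of 23 noradrenergic genes, 11 were lower with siRNA 1, 2 higher and 10 not called (16 lower and 2 higher adjusted over the list alone), with MAOA at -0.62 (adjusted p = 0.000233). The noradrenergic list passed at adjusted p = 5.85e-05 (adjusted p = 0.481 with an estimated correlation). Between siRNA 2 and siRNA 3, 7 of 27 mesenchymal markers were higher with siRNA 2 and 20 were not called (14 higher and 2 lower adjusted over the list alone). The mesenchymal list passed at adjusted p = 7.35e-07 (adjusted p = 0.227 with an estimated correlation). The pairs differed in 2349 genes between siRNA 1 and siRNA 2 (1309 higher with siRNA 1), 3709 between siRNA 1 and siRNA 3 (2068 higher with siRNA 1) and 366 between siRNA 2 and siRNA 3 (256 higher with siRNA 2). The share higher was 55.7% and 55.8% for the pairs with siRNA 1, and 79.6% and 80.3% with library sizes as the only scaling, which moved the median of all genes from 0.0235 and 0.0163 to 0.118 and 0.121. With DESeq2 these shares were 44% and 47%, and without siRNA 1 replicate 1 they were 44.1% and 57.9%. Without siRNA 1 replicate 1 the counts were 951 for siRNA 1 against siRNA 2, 1511 for siRNA 1 against siRNA 3 and 1602 among the 3 siRNAs, and without siRNA 1 replicate 2 they were 1118 for siRNA 1 against siRNA 2 and 2138 among the 3 siRNAs. Without siRNA 2 replicate 1 the count of siRNA 1 against siRNA 2 was 1147, without siRNA 3 replicate 1 and siRNA 3 replicate 2 that of siRNA 1 against siRNA 3 was 2298 and 2421, and that of siRNA 2 against siRNA 3 was 192 without siRNA 2 replicate 2, 228 without siRNA 3 replicate 1 and 202 without siRNA 3 replicate 2.

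Genes called with more than 1 siRNA mostly moved the same way. Of 1296 genes called with both siRNA 1 and siRNA 2, FOS (1.42 and 1.38) among them, 1257 had the same sign, with 588 higher and 669 lower in both where independent lists of these sizes would share 128 and 147. Of 591 genes called with siRNA 1 and siRNA 3, 486 had the same sign and 105 the opposite one, NT5E (1.91 and -1.14) among the latter, with 236 higher and 250 lower in both against 54.7 and 95.4 for independent lists. Of 606 genes called with siRNA 2 and siRNA 3, LUM (-1.17 and -1.60) among them, 598 had the same sign, with 278 higher and 320 lower in both against 23.7 and 48.6. Across genes, which are not independent replicates, fold changes correlated at r = 0.555 (Spearman 0.557), 0.413 (0.416) and 0.619 (0.645) for these 3 pairs of siRNAs. Unchanged groups simulated 20 times against the same scramble libraries gave r = 0.52, 0.511 and 0.501. With 1 library left out, the observed r of each pair ranged from below to above its simulated value. The simulations kept all 8 libraries, though, and the r that shared controls alone give depends on the number of libraries. That range therefore does not show whether r differs from that of unchanged groups. The covariances were 0.121, 0.0926 and 0.11 against 0.0383, 0.0381 and 0.0382 in the simulations. The count of 346 genes that changed the same way with all 3 siRNAs compared with 2.95 higher and 5.99 lower for independent lists and with at most 0 in the simulations, but the 2 scramble libraries were not divided between siRNAs, so part of each excess may come from the shared controls. That count was 126 without siRNA 3 replicate 1 and 156 without siRNA 1 replicate 1. It was 263 without scramble replicate 1, with 27 higher and 236 lower, and 259 without scramble replicate 2, with 185 higher and 74 lower.

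GC-rich genes lay higher with each siRNA than with scramble. Over the 16003 tested genes with a GC value, 84.4% of those tested, the fold change correlated with GC content across genes at a Spearman coefficient of 0.479 in the average, 0.358 with siRNA 1, 0.493 with siRNA 2 and 0.386 with siRNA 3. The genes of TNRC18 and CEP170B, which rose, have a GC content of 67.1% and 66.2%, and those of ELMOD2 and RAB27B, which fell, 33.6% and 35.9%. The slope of log2 CPM on GC content, per 10 points of GC relative to the mean of all libraries, was -0.121 and -0.102 in the scramble libraries and 0.0961 and 0.00668, 0.0927 and 0.0145, and 0.0675 and -0.0548 in those of siRNA 1, siRNA 2 and siRNA 3. With that trend removed from each library, 2576 genes differed in the average, of which 1664 were among the 3268 before, and 309 changed the same way with all 3 siRNAs, of which 154 were among the 346 before. The histone, hypoxia, oxidative phosphorylation and retinoic acid lists still passed in the average. At the preset correlation, the small RNA silencing (adjusted p = 0.00232, up), ATF4 (0.0146, down) and mitochondrially encoded (0.0496, up) lists passed in the average after this correction and not before it. With an estimated correlation their adjusted p was 0.836, 0.836 and 0.994. With siRNA 1 the lists that passed after and not before this correction were the noradrenergic (0.0192, down) and mitochondrially encoded (0.00827, up) lists. With siRNA 2 these were the small RNA silencing (0.000187, up), mitochondrially encoded (0.0185, up), hypoxia (0.00168, down) and retinoic acid (0.0185, down) lists, and with siRNA 3 the small RNA silencing (0.0276, up) and hypoxia (0.00579, down) lists. After the correction, 0 lists passed with an estimated correlation in the average or with any 1 siRNA.

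**Figure D4:**
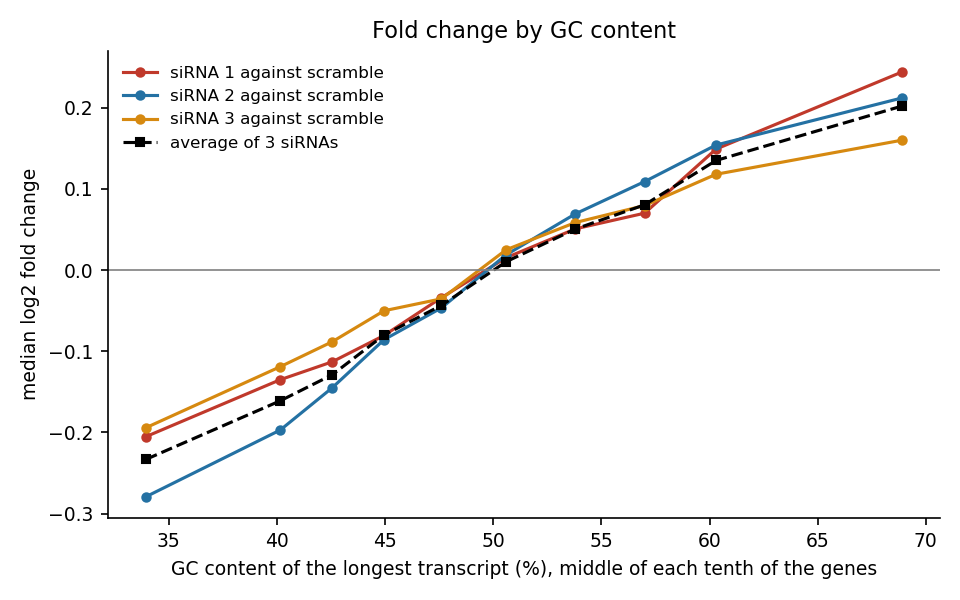
Median log2 fold change against scramble in 10 groups of tested genes of about equal size, ordered by GC content, for each siRNA and for the average of the 3 siRNAs. The median of the average goes from -0.23 in the group with the lowest GC content to 0.20 in the highest.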

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

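The correction for GC content, the search of 3' UTRs and the test of GC bias on the slopes of single libraries were chosen after results were seen, and the other tests were written after the patterns were seen but before their own outcome.

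The effects of the 3 siRNAs differed by tests of the difference itself. Among them, 3627 genes differed, with 2349 between siRNA 1 and siRNA 2, 3709 between siRNA 1 and siRNA 3 and 366 between siRNA 2 and siRNA 3. NT5E (adjusted p = 5.92e-10), MMP1 (5.88e-09), S100A11 (5.88e-09), FLNC (1.23e-08) and SPOCK1 (3.03e-08) had some of the smallest p for any difference among the siRNAs. Of the 25 lists, 7 differed between siRNA 1 and siRNA 2, 11 between siRNA 1 and siRNA 3 and 11 between siRNA 2 and siRNA 3, and 0 of them with an estimated correlation. The mesenchymal list differed at adjusted p = 0.0011 between siRNA 1 and siRNA 2 (adjusted p = 0.481 with an estimated correlation), 1.12e-06 between siRNA 1 and siRNA 3 (0.247) and 7.35e-07 between siRNA 2 and siRNA 3 (0.227).

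Shares of reads outside the gene counts, which were not tested, lay above both scramble libraries in some groups. Reads in no feature came to 6.81% ± 0.3 of the gene counts and summary entries together with siRNA 1. This share was 5.68% ± 0.46 with siRNA 2 and 5.6% ± 0.21 with siRNA 3, against 5.43% ± 0.021 with scramble (SD, n = 2). The share with siRNA 3 exceeds that with scramble by less than its own SD. Reads without a unique alignment came to 24.9% ± 5.1 with siRNA 2, 18.9% ± 2.5 with siRNA 1 and 17.2% ± 0.28 with siRNA 3, against 18% ± 2 with scramble.

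GC-rich genes lay higher with each siRNA than with scramble, and the trend is not one of low-count genes alone, since the correlation of the average fold with GC content was 0.63 among the most expressed genes and 0.479 over all. A GC bias that varies from library to library stays open: the replicates of siRNA 3 differed in slope by 0.122, a share of 0.823 of the difference of 0.149 between the mean slopes of the siRNA and the scramble libraries. All 6 siRNA libraries lay above both scramble libraries, from -0.0548 against -0.102, so a shared response to the siRNAs of GC-rich genes stays open too and was not tested apart from the bias.

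The mesenchymal list passed as higher with siRNA 1 (12 of 27 rose and 3 fell, adjusted p = 0.709 with an estimated correlation) and as lower with siRNA 3 (11 of 27 fell, adjusted p = 0.412 with an estimated correlation). A GC bias does not account for the difference between these siRNAs, whose median was 0.886 before and 0.891 after the GC trend was removed. The list then passed at the preset correlation (adjusted p = 5.02e-06, and adjusted p = 0.431 with an estimated correlation). Across genes, that difference had little relation to GC content (Spearman 0.0714). Against scramble, the median of the list went from 0.382 to 0.251 with siRNA 1 and from -0.501 to -0.387 with siRNA 3. A GC bias may thus account for part of each shift. The list still passed in both at the preset correlation (adjusted p = 0.0145 and 5.67e-06, and 0.657 and 0.361 with an estimated correlation). Whether a larger share of substrate-adherent cells with siRNA 1 contributed was not decided. Of the 10 members with the highest CPM, 9 were higher with siRNA 1 than with siRNA 3, 8 of them past the threshold. COL3A1, VIM and ANXA2 were among them, at 390, 316 and 221 CPM on average. TWIST1 was lower past the threshold (-0.48), which left the test undecided by its rule. The list was flagged on these same values, so the count gives no separate support. It also cannot tell a larger share of such cells from a change within the cells. Off-target effects through the siRNA seeds could not be decided either, since 33.3% of the 3 members lower with siRNA 1 and 0% of 22 others held its leading 7-base word, and for siRNA 3 the shares were 0% of 10 and 13.3% of 15. The siRNA itself, as the design's own difference, stays an open explanation, and COL3A1, ANXA2 and TWIST1 were chosen after their values were seen.

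In 20 simulations of unchanged groups at most 0 genes changed the same way with all 3 siRNAs, against 346 observed. With no gene changed, though, the adjustment passes few genes in any single test. The simulations therefore cannot exclude that random spread in the shared scramble libraries added to the 346 genes. A shift common to many genes of a scramble library is not part of those simulations and stays open, as 27 were higher and 236 lower without scramble replicate 1, and 185 higher and 74 lower without scramble replicate 2. A GC bias may account for part of them, as 45.2% of the 341 with a GC value kept the call after the GC correction. In the average, the 187 that lost it went from a median size of 0.45 (SE 0.0843) to 0.272 (SE 0.0675). The genes that kept it went from 0.637 to 0.552. All 341 kept their sign with each siRNA and 308 their average call. The folds thus shrank in the average, while the folds of the single tests, whose calls ended, were not summarised. Off-target effects of the scramble siRNA could lower genes with its seed word in the scramble libraries alone, and the test was undecided: the word from one part of the genes, ATGTACG, was in 5 of 75 of the genes higher with all 3 siRNAs against 83 of 5854 others in the rest (odds ratio 4.96, one-sided Fisher's exact p = 0.00491), and the word from the rest was in 18 of 88 against 1094 of 5842 (odds ratio 1.12, p = 0.382). TIMM17B, KIAA1549 and SH3GL1 hold ATGTACG, and 17.8% of the genes higher with all 3 siRNAs hold any of the 4 leading scramble words against 5.77% of other genes, but those words were chosen on the same genes, so this decides nothing, and a common effect of losing the circle stays open too.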

How the results depend on the processing

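The correction for GC content, and its use with an estimated correlation, were chosen after the data were seen. No fold change of a named gene past the threshold and no correlation changed its sign, but the balance of higher and lower calls did. With library sizes alone the average had 1930 higher and 1134 lower, against 1413 and 1855. Without scramble replicate 1 the higher calls were 338 in the average, 291 with siRNA 2, 90 with siRNA 3 and 27 of 263 the same way with all 3. Without scramble replicate 2 they were 185 of 259 the same way. For siRNA 2, 1024 higher and 1191 lower became 720 and 553 without scramble replicate 2, 1117 and 922 with library sizes alone and 1279 and 1106 with the stricter filter. For siRNA 1 against siRNA 2, 1309 higher and 1040 lower became 917 and 1165 with DESeq2 and 419 and 532 without siRNA 1 replicate 1. With the value of 1 library left out, where the lone library left in a group is taken to vary like the other groups, the counts of genes ran from 1390 to 3502 for the average, 1277 to 4984 for siRNA 1, 1165 to 2446 for siRNA 2, 394 to 1463 for siRNA 3, 1602 to 4092 among the siRNAs, 951 to 2633 for siRNA 1 against siRNA 2, 1511 to 4130 for siRNA 1 against siRNA 3, 192 to 458 for siRNA 2 against siRNA 3 and 126 to 321 for genes changed the same way with all 3. The lists past the threshold ran from 1 to 6 in the average, 8 to 9 with siRNA 1, 1 to 9 with siRNA 2 and 5 to 8 with siRNA 3, the correlations of fold changes from 0.425 to 0.782 for siRNA 1 and siRNA 2, 0.307 to 0.709 for siRNA 1 and siRNA 3 and 0.454 to 0.816 for siRNA 2 and siRNA 3, and the average change of SLC45A4 from 0.17 to 0.29. The average had 48 genes, 16 higher and 32 lower, with the 6 siRNA libraries pooled, a fit in which differences between siRNAs enter the spread. A 1.5-fold minimum left 585 genes in the average, 1738, 513 and 516 for siRNA 1, siRNA 2 and siRNA 3, 1741 among them, 972, 1580 and 180 for the pairs 1 and 2, 1 and 3, and 2 and 3, and 70 changed the same way. Of these, 265 were higher and 320 lower in the average, 1233 and 505 with siRNA 1, 209 and 304 with siRNA 2, 82 and 434 with siRNA 3, 752 and 220, 1329 and 251, and 149 and 31 for the pairs, and 26 and 44 the same way. Without a low-count filter, 656 genes differed between siRNA 2 and siRNA 3 and 525 changed the same way, and after the GC correction 788 differed between siRNA 2 and siRNA 3 and 7 lists passed in the average, with the small RNA silencing, ATF4 and mitochondrially encoded lists added. The stricter filter left 2 lists in the average. With an estimated correlation 0 lists passed in the average and 0 with siRNA 1, 0 with siRNA 2 and 0 with siRNA 3, before or after the GC correction, and with fry 2, 4, 3 and 5. SLC45A4 passed in the average with library sizes alone (0.28) and without siRNA 1 (0.32), and was 0.13 after the GC correction and 0.15 without siRNA 2. Beyond what pooling does to the spread, the cause was not tested for any of these results that did not keep its side.

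The deviations of same-numbered libraries correlated weakly between groups, at -0.042 to 0.139, and above 0 in 4 of 6 pairs of groups. The slope on GC content was higher in replicate 1 than in replicate 2 with each siRNA. These slopes were 0.0961 and 0.00668, 0.0927 and 0.0145, and 0.0675 and -0.0548. With scramble they were -0.121 and -0.102, so a shared effect of the replicate number stays open. With the number as a block, 4231 genes passed in the average against 3268 without it, and 689 changed the same way with all 3 against 346. The block gave 3418 genes with siRNA 2 against 2215, and 1928 with siRNA 3 against 1212. Between siRNA 2 and siRNA 3 it gave 620 against 366. In siRNA 2 against scramble the block and the stricter filter each ended the p53 call (adjusted p = 0.101 and 0.053).

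DESeq2 gave 3120 genes in the average, 4040, 2423 and 1261 for siRNA 1, siRNA 2 and siRNA 3, 3392 among them and 378 the same way. Over the named genes, 2707 values under an alternative kept their side of the threshold, 248 lost the call and 28 gained it. A value not called in either fit counted as kept even where its sign differed. List tests were not run without a filter or with DESeq2.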

Other observations

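The search of 3' UTRs and the test of junctions of SLC45A4 were chosen after the results were seen.

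Single genes of neurosecretory granules and of signalling pathways changed, while their lists did not pass in the average. SCG2, a granin of secretory granules, rose with siRNA 1 by 1.22 (SE 0.099, adjusted p = 2.95e-07) and with siRNA 3 by 0.51 (SE 0.098, adjusted p = 0.00384), and VGF, a neurotrophin-induced granule protein, rose by 0.83 in the average (SE 0.12) and with siRNA 2 by 0.85 (SE 0.14). In the average, 4 of 17 measured granule genes rose, 1 fell and 12 were not called (4 higher and 2 lower adjusted over the list alone), with adjusted p = 0.822 for the list. The Notch receptor NOTCH3 rose with siRNA 1 by 1.10 (SE 0.11) and siRNA 2 by 0.58 (SE 0.11), while the Notch target HES1 fell with siRNA 2 by 0.76 (SE 0.16) and siRNA 3 by 0.95 (SE 0.17), and of 21 Notch pathway genes 5 rose, 3 fell and 13 were not called in the average (6 higher and 4 lower adjusted over the list alone, list adjusted p = 0.531). Of 25 Wnt pathway genes 2 rose, 3 fell and 20 were not called (3 higher and 3 lower adjusted over the list alone, list adjusted p = 0.928), with the cell cycle regulator CCND1 at 0.60 (SE 0.084) and with MYC at -0.84 (SE 0.093, adjusted p = 9.02e-06) with siRNA 1. Between siRNA 2 and siRNA 3 the Wnt list passed as higher with siRNA 2 (1 higher, 1 lower, 23 not called, 3 higher and 1 lower adjusted over the list alone) at adjusted p = 0.0187 (adjusted p = 0.618 with an estimated correlation). Of 34 axon guidance genes 6 rose, 3 fell and 25 were not called (8 higher and 4 lower adjusted over the list alone, list adjusted p = 0.859), and SEMA3D fell with siRNA 2 by 1.01 (SE 0.2) and siRNA 3 by 1.66 (SE 0.21). Reelin (RELN), a secreted protein of Cajal-Retzius cells, fell with siRNA 3 by 1.34 (SE 0.15, adjusted p = 1.89e-05), and of 9 measured markers of these cells 1 rose, 2 fell and 6 were not called in the average (1 higher and 2 lower adjusted over the list alone, list adjusted p = 0.449).

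The lists of RNA silencing, mitochondrially encoded, cholesterol, chaperone, progenitor and glial genes did not pass in the average before the correction for GC content. TNRC6B, a scaffold of RNA silencing, rose by 0.51 (SE 0.086) and AGO2, the slicing Argonaute, by 0.26 (SE 0.076), and of 23 silencing genes 5 rose, 1 fell and 17 were not called (5 higher and 1 lower adjusted over the list alone, list adjusted p = 0.417). After the GC correction the silencing list passed in the average (adjusted p = 0.00232), with siRNA 2 (0.000187) and with siRNA 3 (0.0276), and the mitochondrially encoded list in the average (0.0496), at the preset correlation, against adjusted p = 0.836, 0.61, 0.595 and 0.994 with an estimated correlation. Of 13 mitochondrially encoded genes 0 changed in the average (0 adjusted over the list alone, list adjusted p = 0.401), and 6 were higher with siRNA 1 than with siRNA 3 and 7 not called (10 higher adjusted over the list alone), MT-ND2 at 0.53 and MT-ND5 at 0.83, at adjusted p = 0.0034 (adjusted p = 0.664 with an estimated correlation). Of 24 cholesterol synthesis genes 1 rose (LSS, 0.28), 1 fell (INSIG1, -0.27) and 22 were not called (1 higher and 1 lower adjusted over the list alone, list adjusted p = 0.859), and of 21 ER chaperone genes 3 rose, HYOU1 at 0.39 among them, 1 fell (DNAJB9, -0.36) and 17 were not called (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.999). Cholesterol synthesis genes passed as lower with siRNA 1 than with siRNA 3 (0 higher, 6 lower, 18 not called, 6 lower adjusted over the list alone) at adjusted p = 0.012 (adjusted p = 0.247 with an estimated correlation). Between siRNA 2 and siRNA 3 no single cholesterol gene was called (0 higher, 0 lower, 24 not called, 1 lower adjusted over the list alone), and the list passed as lower with siRNA 2 at adjusted p = 0.00157 (adjusted p = 0.136 with an estimated correlation). Of 19 neural progenitor genes 1 rose (TNC, 0.62), 1 fell (HES1, -0.56) and 17 were not called (1 higher and 1 lower adjusted over the list alone, list adjusted p = 0.857). Of 9 Schwann and glial markers 1 fell (PMP22, -0.38) and 8 were not called (1 lower adjusted over the list alone, list adjusted p = 0.363).

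Words of 7 bases in 3' UTRs marked genes that were lower with 1 siRNA than in the mean of the other groups, as seed pairing of a short RNA would. The lowest score belonged to ATCATCC for siRNA 1 (z = -11.1, against -4.58 in 100 permutations), ACAGTAT for siRNA 2 (-9.52 against -4.82), GTCACTA for siRNA 3 (-6.99 against -4.79) and ATGTACG for scramble (-8.65 against -4.93), while the highest scores were 4.13, 5.6, 5.37 and 5.87. The highest scores of siRNA 2, siRNA 3 and scramble also lay beyond the permuted highest (5.05, 4.72 and 5.31), so the permutations do not hold all that sets words apart. When the word was chosen in a part of the genes and scored in the rest, both parts chose ATCATCC for siRNA 1 (z = -8.6 and -7.05) and ACAGTAT for siRNA 2 (-7.31 and -6.17). The parts chose different words for siRNA 3, GATCAAT (-2.54) and GTCACTA (-5.7), and for scramble, ATGTACG (-5.31) and TTGTACA (-2.37). The shifts behind the words of lowest score were small, at -0.0884, -0.0328 and -0.0399 for siRNA 1, siRNA 2 and siRNA 3 and -0.106 for scramble.

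The hypothesis is that the siRNAs lie on a back-splice junction of SLC45A4 and act on these genes through their seeds. The 14 acceptor and 17 donor ends of annotated exons can form 159 junctions. Searched on either strand within 20 bases of the junction, 1 of them held a leading word of each of the 3 siRNAs. Leading words lay on 16 junctions for siRNA 1, 4 for siRNA 2 and 16 for siRNA 3. Of 10000 draws of random words, 0.04% gave a junction with words of all 3. Words were drawn independently, while the leading words overlap within siRNAs and between siRNA 2 and siRNA 3. That share therefore does not give how rare such a junction is for overlapping words. The junction found would join the ends of a circle of 641 bases at 141253989 to 141254629 on chromosome 8, on the minus strand of GRCh38. It reads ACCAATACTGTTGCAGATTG before and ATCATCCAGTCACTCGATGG after the junction. In it, ATCATCC of siRNA 1 starts at base 1 after the junction, on the sense strand. TTGATCA of siRNA 2 spans the junction on the sense strand and GATCAAT of siRNA 3 on the antisense strand, but GATCAAT had z = -2.54 in the genes not used to choose it. AGTCACT, another leading word of siRNA 3 (z = -6.52), starts at base 8 after the junction, on the sense strand. The lowest-scoring word of siRNA 2, ACAGTAT, is there only on the antisense strand, from 16 bases before the junction, and that of siRNA 3, GTCACTA, is absent. The 4 leading words of scramble were absent from all 159 junctions. The sequences of the siRNAs are not given in the sources used here, the circle was not measured, and the idea was found and tested on the same data, so it remains a hypothesis.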
